A study of Mus musculus with 4 samples.

How the data were processed

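Microglia were profiled by droplet single-cell RNA sequencing in mice given simulated galactic cosmic radiation or sham handling. Per the labels' protocols, male and female C57BL/6J mice aged 6 months received 100 cGy to the whole body from a sequence of 5 ion species, or were handled alike without beam. The genotype labels read C57BL/6 for replicate 1 and C57BL/7 for replicate 2. Behaviour was tested 48 to 51 days later, and hippocampus and overlying cortex were taken at 53 days. Cells were cleaned in 40% Percoll, stained for CD11b, a surface protein of myeloid cells, and tagged with barcoded antibodies against CD45 and MHC class I. Live CD11b-positive singlets were sorted and loaded on 10x 3′ kits of version 3.1 as 2 pools, each with a gene expression library and a hashtag library.

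The deposited values are whole-number UMI counts per gene and tag counts per hashtag for each cell barcode, not normalized, made with Cell Ranger 7.0.1 on mm10 per the submitters' processing notes. The matrices hold barcodes that the pipeline had called as cells, as the names of the deposited counts show. Each matrix has 32285 gene rows and 12 hashtag rows. Pool 1 holds 9516 barcodes with 92987197 gene UMIs, and pool 2 holds 10893 barcodes with 102182792. The files pair no hashtag with a sex, a treatment or an animal. Hashtags were therefore not put in groups, and no comparison of irradiated with sham mice or of females with males was made. Those comparisons, with their gene list tests and shares by group, had been planned before the data were examined and were not run. The 12 hashtag names are codes, and no meaning was taken from them.

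Hashtags were assigned per pool with HTODemux in Seurat 5.3.0 on centred log ratios across cells, with a positive quantile of 0.99. Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, which left 20189 of 20409. Scrublet, run per pool with an expected rate of 0.08, called 1 of them. A caller that marks so few has not worked, so only the 3046 cross-hashtag doublets were in effect removed, and doublets within a hashtag remain. The 17143 barcodes kept comprise 16380 with 1 hashtag and 763 with none. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5 were used in scanpy 1.11.5. No cluster had over 57.5% of its cells from 1 pool, and pools were not integrated.

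The cell type markers were fixed before the data were examined. The rule that turns them into cluster names was not: it was written after a first clustering had been seen, and amended once after the alternative clusterings had been seen. The amendment left the names of the main clusters as they were. A marker was raised at 2 times its level in all other cells or more. A cluster was taken for another cell type when at least 3 markers of that type were raised, and either at least 3 microglia markers were halved or that type had more markers among the leading genes. It was named for the type with most leading markers, and stayed unnamed with none. Of the others, a cluster stayed unnamed when its median UMI count was below the median of all cells divided by 3 in a pool and no microglia marker led it. The rest, with at least 3 microglia markers seen in at least 25% of cells, were called microglia-like. They took the state with most leading markers, then the highest placed, among states with at least 3 markers raised. Leading genes of a cluster are the 10 with the highest fold over all other cells among genes seen in at least 25% of its cells.

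Counts of microglia-like cells were summed per hashtag and pool, giving 24 summed libraries of 2712046 to 9792348 UMIs. CPM are counts scaled to the summed total of each library. A gene list level is the log2 of the summed CPM of its members. There were 21 lists, fixed before the data were examined. Named genes follow a rule also fixed then: of each list, the 4 members with the highest mean CPM over hashtags, and the 10 genes with the highest ratio of largest to smallest CPM over hashtags among those with a mean of at least 20 CPM. Some genes that the rule names are not reported here. Genes named outside it were chosen after their values were seen, as the text says. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Where a CPM lay under 3 counts of the smallest summed library, the ratio was taken against that floor.

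The tests of genes among hashtags and between pools were added after the files and some values per hashtag had been seen. They used edgeR 4.0.16, with TMM scaling, its low count filter, a quasi-likelihood fit with pool and hashtag as terms, and Benjamini-Hochberg adjustment at 0.05. The test among hashtags is a joint F-test of the hashtag terms. Its only replicates are the 2 pools. Every hashtag is in both, and the common dispersion was 0.000907. The labels call the pools biological replicates but do not say which animals each holds, and both hold the same 12 hashtags, so these p-values measure only the spread between pooled libraries, not between mice or conditions. On simulated counts for the test among hashtags over 12755 genes, 98% of 100 genes with a fold of 2 in 1 hashtag were called, 97% of 100 genes with a fold of 1.5 in 6 hashtags, and 1 of 12555 unchanged genes. For the test between pools, 91% of 200 genes with a fold of 1.25 were called and 6 of 12555 unchanged genes. In both simulations the changed genes were drawn from the better expressed genes only. Counts followed the dispersion trend fitted to these data, so a gene carried by 1 barcode was not simulated.

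Repeatability of the list levels was added after the data had been seen. It is the correlation between pools over the 12 hashtags, with Pearson's r and Spearman's rho, two-sided permutation p from 100000 resamples, and adjustment over 20 lists. The list of X- and Y-linked sex markers was left out of it, because its values fall into separate clusters. On simulated unrelated pools 4.5% of lists had an unadjusted p under 0.05, and 92.5% did where the pools shared their hashtag values. The software also comprised R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.

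Alternatives planned before the data were examined were hashtag assignment at a quantile of 0.999 or by the largest count being at least 3 times the second and at least 10, other cell filters, Leiden resolution 1, no scrublet removal, all singlets, TMM-scaled CPM and leaving out each pool. DESeq2, its size factors, no low count filter, models without the pool or the hashtag, leaving out single libraries or hashtags, leaving out cluster 3, and the mean of log2(CPM + 1) over list members were tried for the added results and chosen after seeing the data. Positions are from GENCODE M21 on GRCm38, to which 32235 of the 32285 gene IDs matched. Counts at the 3′ end cannot separate near-identical copies such as Hspa1a and Hspa1b, so the values of such pairs are uncertain.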

Results

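The series asked how simulated galactic cosmic radiation changes microglia, the resident immune cells of the brain, in male and female mice. It holds 2 pooled gene expression libraries and the 2 hashtag libraries that go with them. Pool 1 had a median of 9737 UMIs and 3567.5 genes per barcode, and pool 2 had 9156 UMIs and 3444 genes. Because the hashtags are paired with no sex or treatment in the files, the values below describe cells, states and the 12 hashtags, and no effect of radiation or sex was estimated.

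Nearly all sorted cells were microglia-like. Of 17143 cells, 97.1% (95% interval 96.8 to 97.3) fell in clusters named microglia-like, 97.2% in pool 1 and 97.0% in pool 2. Among markers of other cell types, border-associated macrophage markers lay between 8.61 and 75.3 CPM in the microglia-like clusters, highest in cluster 2. The neutrophil markers were nearly all Csf3r, at 415, 484, 494 and 673 CPM in clusters 0 to 3, where Camp, at most 1.31 CPM, was the next highest. In cluster 6, S100a8 stood at 1762, S100a9 at 1682 and Camp at 556 CPM, and 1 barcode held most of the S100a9 UMIs. A small cluster of 123 cells, 0.717% (0.597 to 0.855), was led by the MHC class II genes H2-Eb1, H2-Aa, H2-Ab1 and Cd74 and by Mgl2, which myeloid antigen-presenting cells express. It had 7253 CPM of the microglia markers against 20839 in all other cells, and 1980 CPM of border-associated macrophage markers against 12.0. It also carried markers of monocytes and dendritic cells, and it stayed unnamed. A further 381 cells, 2.22% (2.01 to 2.45), had a median of 1024 UMIs. They were led by Gm42418, which overlaps a ribosomal RNA repeat, held 1126 CPM of neuron markers against 10.8 in all other cells, and also stayed unnamed, although 10 of 10 microglia markers were kept.

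The microglia-like cells formed 3 large clusters and 2 small ones. Cluster 0, 4081 cells, was led by ribosomal protein genes such as Rps4x and Rpl39. Cluster 1, 5908 cells, was led by Atg4a, an autophagy protease, and by histone genes. Cluster 3, 6092 cells, was led by AY036118 and unnamed noncoding transcripts. It had a median of 4148 UMIs and 2.20% mitochondrial UMIs, against 12450 UMIs and 0.862% in cluster 1. Cluster 6, 172 cells or 1.00% (0.860 to 1.16), was led by the chemokines Ccl4 and Ccl3, the lipase Lpl, the cell cycle inhibitor Cdkn1a and the growth factor Csf1. It was named a cytokine state, although disease-associated markers were as frequent among its leading genes. It also held proliferating cells, with Top2a at 180 and Mki67 at 125 CPM, and 46 cells were named proliferating with the looser cell filter and 55 with the ratio rule for hashtags.

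Cluster 2, 386 cells or 2.25% (2.03 to 2.48), was led by the interferon-induced genes Ifit3, Ifit2, Oasl2, Slfn5, Ifi204, Irf7 and Isg15, and was named interferon-responsive. The cluster was mixed. With the stricter cell filter of at least 1000 genes and at most 5% mitochondrial UMIs, its cells were divided between an interferon-responsive cluster and a cluster led by Axl, Vcam1 and Apoe that was named disease-associated. Relative to all other microglia-like cells, and among the lists with no leading gene of the cluster, MHC class I presentation was 1.90-fold higher in cluster 2, in 12 of 12 hashtags, with B2m at 1563 against 861 CPM and H2-D1 at 615 against 279 CPM. The homeostatic list was 0.881-fold, lower in 12 of 12 hashtags, with Tgfbr1 at 2339 against 2860 CPM. MHC class II presentation was 1.38-fold higher in 11 of 12. The lipid and cholesterol list was 1.81-fold higher in 11 of 12 hashtags, with Apoe at 1251 against 178 CPM. Its next most abundant members lay at 1.12-fold (Abca1), 0.722-fold (Lrp1) and 1.27-fold (Soat1), so the rise was mostly Apoe. The disease-associated list, which also holds Apoe, was 1.22-fold higher in 10 of 12. With the stricter filter the interferon-responsive cluster differed by only 0.02 on the log2 scale for lipid and cholesterol, against 0.85 in cluster 2, and by 0.01 for the disease-associated list, against 0.28. Alternative activation, 0.12 in cluster 2, lay at -0.19 with that filter and at -0.15 at Leiden resolution 1. Ribosomal proteins were 1.38-fold, and all remaining lists lay between 0.942-fold (cell cycle) and 1.17-fold (oxidative stress). The comparison includes cluster 3, with few UMIs, where ribosomal proteins were 0.193-fold and complement and phagocytosis 0.649-fold, and in cluster 0 they were 1.83-fold and 1.36-fold. Against the other microglia-like cells without cluster 3, added after the data had been seen, cluster 2 lay at 1.73-fold for MHC class I (12 of 12 hashtags), 0.851-fold for the homeostatic list (12 of 12) and 1.87-fold for lipid and cholesterol (11 of 12). MHC class II lay at 1.29-fold (9 of 12), ribosomal proteins at 1.17-fold (10 of 12) and complement and phagocytosis at 1.05-fold (7 of 12).

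In cluster 6, the lists without a leading gene of that cluster lay higher for glycolysis (1.82-fold), MHC class II (1.73-fold), MHC class I (1.58-fold), oxidative stress (1.52-fold), nuclear oxidative phosphorylation (1.41-fold) and ribosomal proteins (1.26-fold), each in 12 of 12 hashtags, and for interferon (1.61-fold) in 10 of 12. In the class II list Cd74 stood at 194 against 21.5 CPM, while H2-DMa, H2-DMb1 and H2-Oa lay at 1.11-fold, 1.12-fold and 0.966-fold. Of the interferon list, Ccl12 stood at 256 against 53.2 CPM and Ifi27l2a at 140 against 12.4, while Bst2 lay at 1.68-fold and Trim30a at 0.902-fold. Without cluster 3 among the other cells, glycolysis lay at 1.69-fold, oxidative stress at 1.39-fold, ribosomal proteins at 1.06-fold and nuclear oxidative phosphorylation at 1.24-fold, while the last was 1.59-fold in cluster 0. The cell cycle list, which holds a leading gene, was 7.18-fold. Gapdh stood at 748 against 315 CPM and the antioxidant enzyme Prdx1 at 280 against 116 CPM. The homeostatic list was 0.830-fold, lower in 12 of 12 hashtags, with the fractalkine receptor Cx3cr1 at 2492 against 3253 CPM.

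HTODemux called 16461 barcodes with 1 hashtag, 80.7% of all. It called 1426 barcodes of pool 1 and 1627 of pool 2 with several hashtags, and 4.39% of all barcodes with none. The hashtags held 618 cells (46N) to 2029 cells (12L), with a median of 1563. Median depth was similar, from 8883 UMIs per cell in 37R to 10001 in 37B. The share of cluster 3, with few UMIs, ranged from 29.5% in 11N to 38.8% in 37L, with a median of 33.5%. The share of cluster 2, singled out after its values were seen, was 11.4% in 37R, 10.7% (8.52 to 13.2) in pool 1 and 11.9% (9.86 to 14.3) in pool 2. In the other hashtags it lay between 0.671% and 2.36% in pool 1 and between 0% (12R, 0 of 582 cells, upper bound 0.632%) and 2.48% in pool 2. Most of these 37R cells were not interferon-responsive under the stricter filter: of 180, 56 kept that name and 119 were named disease-associated. At Leiden resolution 1, 60 were named interferon-responsive and 120 border-associated macrophage-like, although the microglia markers of that cluster were kept. Under the stricter filter the interferon-responsive share of 37R was 3.67% (2.39 to 5.37) and 4.26% (2.99 to 5.88), against at most 1.78% (12B) and 2.25% (46R) in any other hashtag. The intervals of 12B and 46R reached 2.97% and 3.75%. The 119 cells had 101 CPM of Axl, a receptor tyrosine kinase, and 1055 CPM of Apoe, against 9.64 and 183 in the other microglia-like cells of 37R, with 11.9 CPM of Ifit3 against 3.80, 313 CPM of interferon-responsive markers against 129, and 2326 CPM of P2ry12, a microglial purinergic receptor. They also had 80.6 CPM of border-associated macrophage markers against 14.7, Mrc1 at 65.7 against 12.8 CPM, and a median of 11060 against 8587 UMIs, and doublets within a hashtag were not removed.

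**Figure D1:**
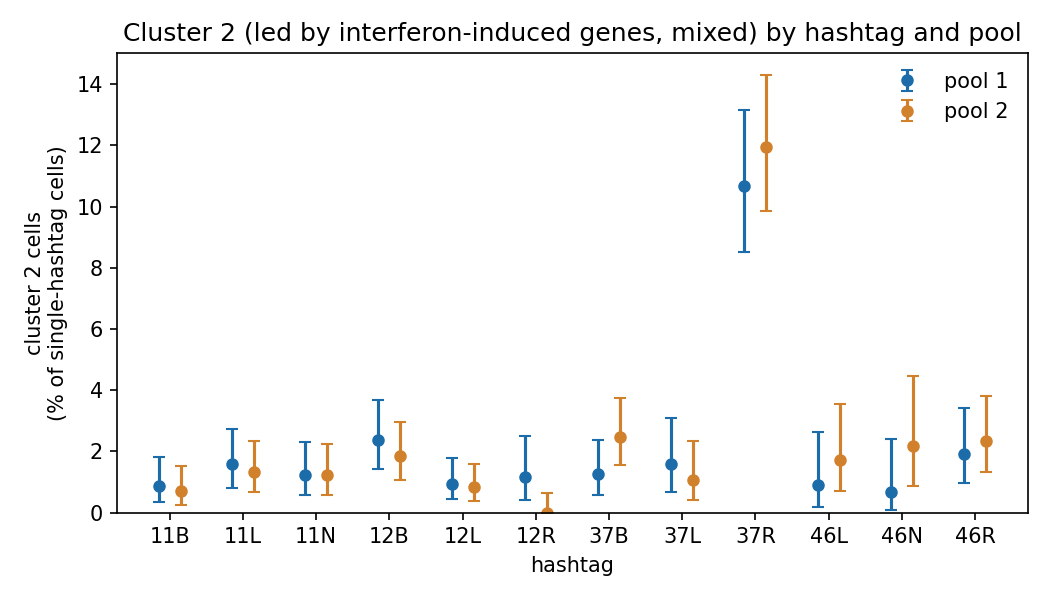
Share of cluster 2, named interferon-responsive, among cells with 1 hashtag (y axis, %) for each of the 12 hashtags (x axis), in pool 1 (blue) and pool 2 (orange). Points are shares and bars exact 95% intervals for counting error; 37R lies at 10.7% and 11.9% and every other hashtag at or below 2.48%, and the cluster mixes 2 states.

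Over the 20 lists without the sex markers, the level of the highest hashtag lay between 1.06 times (nuclear oxidative phosphorylation) and 1.76 times (interferon) that of the lowest. The interferon list, of genes induced by interferon, ranged from 646 CPM in 12R to 1135 in 37R, with a median of 772. Outside cluster 2 it stood at 816 (pool 1) and 768 CPM (pool 2) in 37R, 727 and 728 in 46N, and 582 and 608 in 11N, the lowest. Of its 28 tested members 21 differed among hashtags in edgeR's test over all genes and 24 adjusted over the list alone. Its most abundant members, Trim30a, Bst2, Herc6 and Parp14, were all highest in 37R, with Bst2 at 112 CPM there and 74.7 in 12L. Ifit3 itself was not called (adjusted p = 0.282, edgeR). MHC class I presentation ranged from 1859 CPM in 12R to 2431 in 37R, with 8 of 12 members called and 9 adjusted over the list alone. Outside cluster 2 it stood at 2210 and 2228 CPM in 37R and 2156 and 2067 in 46N. B2m, H2-D1 and H2-K1 were highest in 37R, H2-D1 at 419 CPM against a median of 278, while H2-T23 was highest in 46N. MHC class II presentation ranged from 314 to 357 CPM, and 1 of 7 members was called, also adjusted over the list alone. Its abundant members were H2-DMa, H2-DMb1, H2-Oa and Cd74.

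Genes of the homeostatic program, which mark resting microglia, ranged from 29622 CPM in 37R to 32067 in 46R. All 16 were called, also adjusted over the list alone, with small ratios, among them Cx3cr1 1.09, P2ry12 1.13 and Tgfbr1 1.18 between the highest and lowest hashtag. The disease-associated list ranged from 12246 to 13676 CPM, with 12 of 20 members called and 15 adjusted over the list alone. The protease Ctsd was highest in 46N, at 4779 CPM, and lowest in 11L, at 3924, and Fth1 was highest in 37R. Tyrobp had a ratio of 1.07, as had Trem2, which was not called (adjusted p = 0.0695, edgeR). Complement and phagocytosis ranged from 20748 CPM in 11B to 22910 in 46N, with 16 of 18 called and 17 adjusted over the list alone, and C1qa, C1qb and C1qc highest in 46N and Mertk in 12R. Synapse pruning, which shares C1qa, C1qb, C1qc and Cx3cr1, had 11 of 14 called and 13 adjusted over the list alone. The lysosome list, with Ctsd, Ctss and Lgmn among its abundant members, had 18 of 27 and 19.

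The immediate early and dissociation list, genes induced within minutes of cell stress, ranged from 1565 CPM in 37R to 1977 in 11N, with 18 of 22 called and 18 adjusted over the list alone. Rhob, Btg2, Jund and Junb were highest in 11N, Jund at 201 CPM against 120 in 37R. The list was 0.401-fold in cluster 3, whose share was lowest in 11N, and without cluster 3 it was highest in 46L, at 2162 CPM, and lowest in 37R, at 1757. The cytokine and NF-kB list ranged from 1423 CPM in 37L to 1736 in 46R, with 14 of 21 called and 15 adjusted over the list alone. Nfkb1 was highest in 11B, Cd14 in 12L and Nfkbia, an inhibitor of NF-kB, in 37R, while Cd86 was not called (adjusted p = 0.362, edgeR). Alternative activation, led by Tgfb1, Il4ra, Socs3 and Mrc1, had 4 of 5 called and 5 adjusted over the list alone. Oxidative stress, with Cyba, Ncf1 and Gpx4 among its abundant members, had 14 of 19 and 15. The p53 target and DNA damage list ranged from 621 to 689 CPM, with 6 of 21 called and 6 adjusted over the list alone, and Ddit4 went from 25.5 CPM in 11B to 104 in 37R, while Btg2 had a ratio of 1.42. Ddit4 is also in the glucocorticoid-responsive set described for 11B below, and Btg2 in the immediate early list. Bax and Mdm2, with ratios of 1.12 and 1.23, were not called (adjusted p = 0.735 and 0.416, edgeR). Senescence, led by Hmgb1, Glb1, Il1a and Hmgb2, had 3 of 12 called and 5 adjusted over the list alone. The cell cycle list, led by Tubb5, Pcna, Mcm3 and Stmn1, had 3 of 23 and 3.

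Mitochondrially encoded transcripts ranged from 11992 CPM in 11N to 14475 in 37R, with 11 of 13 called and 13 adjusted over the list alone, and mt-Co3, mt-Atp6, mt-Cytb and mt-Co1 all lowest in 11N and highest in 37R. The median mitochondrial percent of cells was also highest in 37R, at 1.36%. These transcripts were 2.10-fold in cluster 3, which made up 36.6% of the cells of 37R and 29.5% of those of 11N, and without cluster 3 they ranged from 10287 CPM in 11B to 11870 in 37R. Nuclear oxidative phosphorylation genes, led by Cox4i1, Cox8a, Cox7c and Atp5g2, ranged from 6659 to 7026 CPM, with 7 of 83 called and 0 adjusted over the list alone. Ribosomal proteins, led by Rps29, Rplp1, Rps24 and Rps21, ranged from 44989 to 49960 CPM, with 78 of 92 called and 84 adjusted over the list alone, among them Rps6ka3, a kinase and not a ribosomal protein. They were 0.193-fold in cluster 3, and without it were highest in 37R, at 58192 CPM, instead of in 11N. Glycolysis, led by Gapdh, Hk2, Eno1 and Pkm, had 3 of 13 and 3. The lipid and cholesterol list, led by Abca1, Lrp1, Apoe and Abcg1, had 5 of 18 called and 8 adjusted over the list alone, and Apoe, at 133 CPM in 37L and 289 in 46N, was not among the called genes (adjusted p = 0.0695, edgeR).

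**Figure D2:**
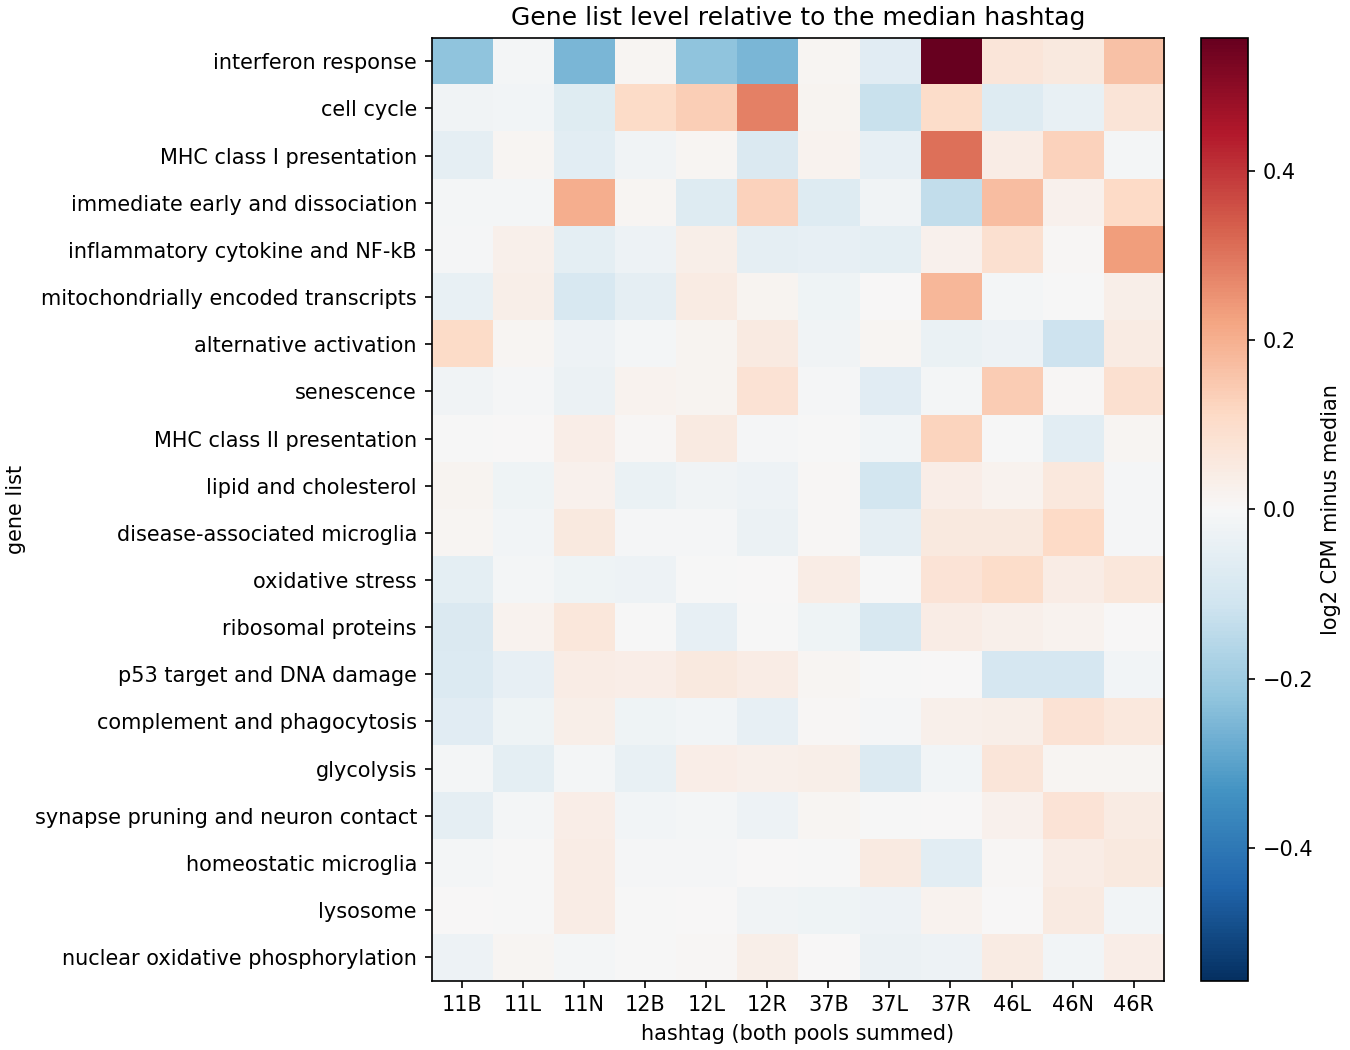
Level of 20 gene lists (rows) in each of the 12 hashtags (columns, both pools summed), as log2 CPM minus the median hashtag (colour). The interferon list had the widest range, 0.81 on the log2 scale, and nuclear oxidative phosphorylation the narrowest, 0.08.

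Of all genes with a mean of at least 20 CPM, the 10 with the widest ratio over hashtags held Xist, Tsix, Uty, Eif2s3y and Ddx3y, which are sex-linked. S100a8 and S100a9, abundant in neutrophils, reached 413 and 394 CPM in 12R. In the library of 12R in pool 2, 1 barcode held 3848 of the 3852 S100a9 UMIs, so this value is that barcode and not the hashtag, and the edgeR call of S100a9 rests on it. Negr1, a cell adhesion gene, reached 119 CPM in 37R against 3.63 in 37L, and its mean of the pools in 37R was 120 ± 17.0 CPM (SD, n = 2). The chemokines Ccl4 and Ccl3 were highest in 46R, at 115 and 59.6 CPM, with medians of 23.2 and 12.1.

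In a joint edgeR test, added after the data had been seen, 3441 of 13039 genes (26.4%) differed among hashtags, 4775 at an unadjusted p under 0.05, and 1304 of the called genes had a highest hashtag at least 1.5 times the lowest. DESeq2 called 2136. For 59 of the called genes the SD between pools in the highest hashtag exceeded 50% of its mean. These tests set hashtags against the spread between 2 pooled libraries, so they show that hashtags differ, not that conditions or mice do.

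The genes named here were chosen by their small p after the values had been seen. Fkbp5 (ENSMUSG00000024222), a glucocorticoid-induced cochaperone on chromosome 17 at 28399094 to 28517527 of GRCm38, ranged from 237 ± 14.9 CPM in 11B to 851 ± 5.23 in 37L (SD, n = 2 pools; adjusted p = 3.84e-48, edgeR). The transcription factor Zeb2 was highest in 11B, at 2193 CPM, and lowest in 46N, at 1193. The chaperones Dnaja1 and Hsp90ab1 were highest in 11B, at 280 and 623 CPM, against medians of 138 and 380. Nlrp3, an inflammasome sensor, was highest in 46R, at 143 ± 7.76 CPM (n = 2), against a median of 69.7. Axl was highest in 37R, at 20.6 ± 0.150 CPM (n = 2), against a median of 2.89. Jun ranged from 88.9 CPM in 12L to 257 in 46L, and the cyclin Ccnd3 from 1021 in 11B to 1593 in 37R.

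**Figure D3:**
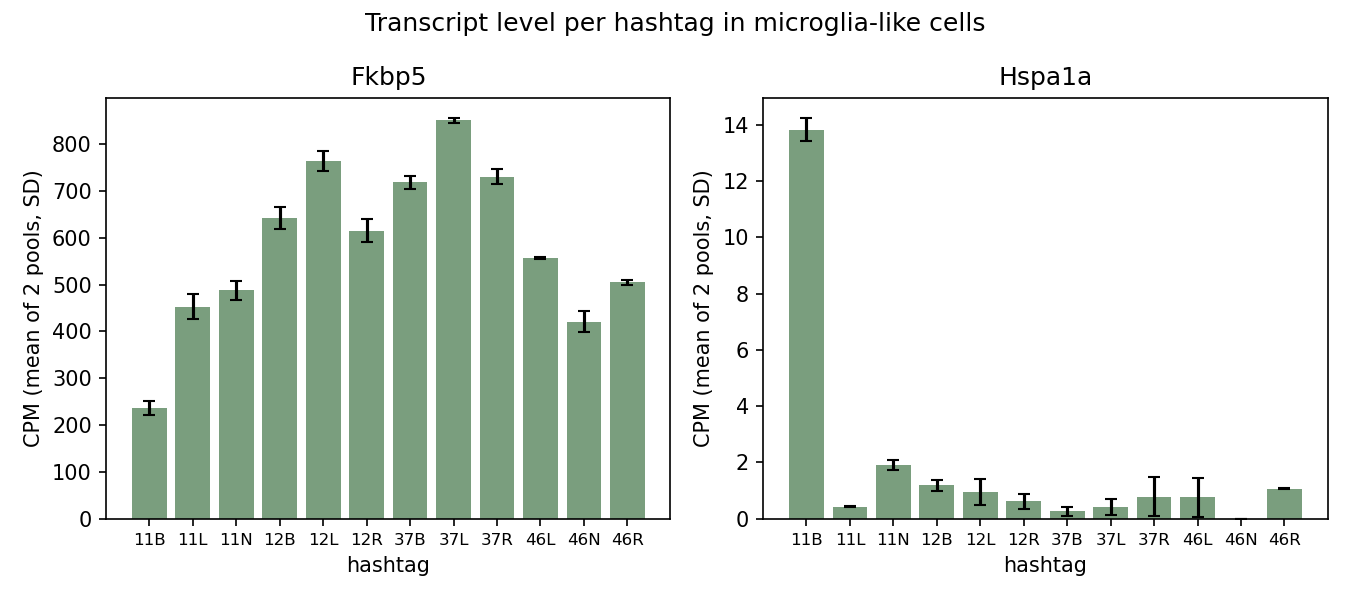
CPM of Fkbp5 (left) and Hspa1a (right) in microglia-like cells of each of the 12 hashtags (x axis). Bars are means of the 2 pools with SD; Fkbp5 is lowest and Hspa1a highest in 11B.

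With the hashtag in the model, 106 genes differed between the pools in edgeR's test, also added after the data had been seen, 81 higher and 25 lower in pool 2. Ribosomal protein genes made up most of the rise: 57 of 92 were called higher, by a median of 0.07 on the log2 scale over the 92. The 92 were picked by symbol and include Rps6ka3, a kinase and not a ribosomal protein. Without the hashtag in the model 6 genes were called. Each pool is 1 library whose hashtags were prepared together, so this test sets 2 libraries apart and has no replicate of either.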

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

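The planned comparisons of radiation and sex, their gene list tests and the shares by group were not run, nor were their alternatives, because hashtags carry no group. The tests among hashtags and between pools, the repeatability of lists and the share of 37R, with all their alternatives, were chosen after seeing the data. The microglia-like share moved from 97.1% to 96.2% at Leiden resolution 1, 99.5% with at least 1000 genes and at most 5% mitochondrial UMIs, and 96.4% with 200 genes and no limit. In that order, the cytokine, disease-associated or proliferating state moved from 1.00% to 3.02%, 3.75% and 1.17%, and non-microglial myeloid cells from 0.717% to 1.53%, 0.478% and 0.461%. At resolution 1 the latter include 184 cells named border-associated macrophage-like that kept the microglia markers. The interferon-responsive share fell to 1.33% under the stricter filter, and low-UMI cells rose to 3.19% under the looser one, while the stricter filter left none. In 37R, the interferon-responsive share moved to 3.67% (pool 1) and 4.26% (pool 2) under the stricter filter. At resolution 1 it was 8.60% in pool 1 and 8.24% in pool 2, and a second cluster, with a median of 4703 UMIs, also took that name. Negr1 led that cluster, followed by Oasl2, with Ifi204 and Stat2 among its other leading genes. Oasl2, Ifi204 and Stat2 belong to the interferon list. The ratio rule called 89.0% of barcodes with 1 hashtag and 6.59% with several. The higher HTODemux quantile gave 82.6%, 9.37% and 8.02% with none.

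Among hashtags, DESeq2 called 2136 genes against 3441, and the cause was not tested. Without the pool as a replicate block 3222 were called, of which 3209 were shared. Other settings gave 2969 to 4144, with 3431 without the sex markers, and leaving out 1 library gave 3166 to 3550. Between pools, 6 genes were called without the hashtag in the model against 106, other settings gave 85 to 128, leaving out 1 library gave 92 to 141, and DESeq2 gave 117 over a filtered set of genes. Repeatability held for 14 of 20 lists on summed CPM for 7 on mean log values, where the cause was not tested, and for 15 without cluster 3. List ranges moved beyond the spread between pools for 13 of 20 lists on that scale, for 7 without cluster 3, for 3 with all singlets, for 1 with TMM and for 0 with the ratio rule. The class II range rose to 1.17 with all singlets, which add the class II-rich cluster. Alternative activation in the interferon-responsive cluster changed sign with the clustering, from 0.12 to -0.15 and -0.19. Leaving out a pool kept the 5 class shares within their intervals, but not cluster 0 (22.7% and 24.8%, interval 23.2 to 24.5) and cluster 1 (35.7% and 33.3%, interval 33.8 to 35.2).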

Other observations

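All tests in this part were chosen after the patterns had been seen, and what would count for or against each explanation was set down after the tests had been run, so they can argue against an explanation but establish none. The hashtags carried a signature that both pools shared. Over 3898 autosomal genes, each of the 12 hashtags of pool 1 resembled the hashtag of its own name in pool 2 most, with correlations across genes of 0.365 to 0.804 against at most 0.474 with any other name; genes are not independent replicates. Of 20 gene lists, 14 were correlated between pools over the hashtags at an adjusted permutation p under 0.05 on Pearson's r. The immediate early list had r = 0.94 (permutation p = 2e-05, adjusted 0.0002) and rho = 0.85 (permutation p = 0.00097, adjusted 0.00323), and r = 0.93 without its 2 farthest hashtags, but on mean log values r was 0.62 (permutation p = 0.0313, adjusted 0.0626) and rho 0.69 (permutation p = 0.0174, adjusted 0.058), so its call was lost on that scale. For the interferon list r was 0.78 (permutation p = 0.00422, adjusted 0.00703) and rho 0.64 (permutation p = 0.0297, adjusted 0.0466), and r fell to 0.45 without 37R and 11N, so that relation rests on those hashtags. The mitochondrially encoded list fell likewise from r = 0.75 (permutation p = 0.00523, adjusted 0.00805; rho 0.64, permutation p = 0.0303, adjusted 0.0466) to 0.25. The cell cycle list had r = 0.08 (permutation p = 0.811, adjusted 0.811) and rho = 0.28 (permutation p = 0.376, adjusted 0.443).

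Of the X- and Y-linked list, 10 of 10 members were called among hashtags, also adjusted over the list alone. The sex-linked transcripts fell into separate clusters of hashtags. Xist stood at 1226 CPM in 37B, 1215 in 37L, 1311 in 37R, 1192 in 46L, 1219 in 46N and 1169 in 46R, and at 17.8 in 11B, 16.4 in 11L, 13.4 in 11N, 17.3 in 12B, 15.7 in 12L and 15.6 in 12R. Ddx3y stood at 4.23, 4.15, 4.94, 4.02, 3.09 and 4.19 CPM in the first of these sets and at 91.8, 81.1, 78.1, 84.9, 81.1 and 81.8 in the second, in that order. No other value was compared between these sets, and no sex was assigned.

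Hashtag 37R held a larger share of cluster 2, named interferon-responsive, and no biological explanation was tested since its condition is not known. Chance in the cells sampled is argued against in the main clustering: its lowest lower bound was 8.52% against a highest upper bound of 4.45% elsewhere (46N, pool 2), although the bounds of the stricter filter overlapped. The share was at least 11.5% under the ratio rule, so it did not depend on the HTODemux rule. Both rules read the same tag counts, and the ratio rule called more barcodes, so wrong hashtags stay open. Cells or RNA of the class II-rich cluster stay open: of 44 genes of at least 50 CPM raised at least 2 times in both pools in the 119 cells named disease-associated, 21 (47.7%, 32.5 to 63.3), among them Negr1 and Vcam1, lay above their level in both its class II-high and its class II-low cells, but Apoe and Mrc1 did not. These genes were picked from the same cells and are not independent replicates, so the interval is nominal and decides nothing. The cluster name is not borne out in 37R. Under the stricter filter 31.1% (24.4 to 38.4) of these cells stayed interferon-responsive and 66.1% joined the state led by Axl, Vcam1 and Apoe. In the other hashtags 67.7% (60.7 to 74.1) and 24.9% did. With that filter, a merging of states may thus account for most of the excess under the interferon-responsive name. At Leiden resolution 1 more of the excess stayed under that name. There 37R held 8.60% (6.66 to 10.9) and 8.24% (6.49 to 10.3), against at most 2.36% (12B) and 2.81% (46N) in any other hashtag. How much merging accounts for thus depended on the setting. Under the stricter filter 37R had an excess of the disease-associated state, 12.0% and 12.2% of its cells against at most 6.13% in any other hashtag. At Leiden resolution 1 that state held 3.47% and 4.76% of 37R, against up to 6.14% and 5.94% elsewhere. The name had shifted there: of the 180 cluster 2 cells of 37R, 120 were named border-associated macrophage-like and 0 disease-associated. Vcam1, Axl and Apoe were among the leading genes of a cluster with that border-associated name.

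Hashtag 11B had the highest summed heat shock and the lowest summed glucocorticoid-responsive transcripts, in gene sets picked after seeing the data. Heat shock genes summed to 1871 and 1940 CPM in its pools, against at most 1356 and 1414 elsewhere, and glucocorticoid-responsive genes to 613 and 565, against at least 926 and 890. Of the 8 glucocorticoid-responsive genes, Fkbp5, the most abundant, had the largest gap in CPM, at 237 against a median of 611 elsewhere. Relative to the median, Ddit4 (25.5 against 78.0 CPM) and the scarce Zbtb16 (0.613 against 3.03 CPM) lay lower. Tsc22d3, Zbtb16 and Klf9 were not lowest in 11B, and Klf9 was not called (adjusted p = 0.306, edgeR). A general activation during dissociation is argued against only for abundant genes: 11B ranked at best 10 of 12 for the sum of 18 immediate early genes. Rhob, Btg2, Jund and Junb lead that sum, while Fos and Egr1 reached at most 2.61 and 1.66 CPM in clusters 0 to 3. Activation seen mainly in scarce genes, warming, or another stress that spares the abundant genes stays open. Whether lower depth contributed was not decided. The median UMI count of 11B ranked 5 from the lowest, so it was not the shallowest hashtag. The 4 hashtags below it had at most 1366 CPM of heat shock and at least 890 of glucocorticoid-responsive genes. That outcome was fixed, because 11B was picked as the extreme of all 12 hashtags. No biological explanation was tested.

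Each pool is 1 library, too few for the splits to decide on chance in the genes that differ between pools: of 97 splits that reassign the pool number within hashtags, 1, the real one, gave as many as 106 genes, and the highest other gave 50.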
